A study of Mus musculus with 2 samples.

How the data were processed

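Gene expression was measured in peeled mouse epidermis on 2 one-colour Agilent arrays, 1 per genotype. The control array held RNA of the Nfkbiz flox/flox genotype. The knockout array held RNA of the Nfkbiz flox/flox genotype with the K5-cre transgene, in which the recombinase is driven by the keratin 5 promoter of basal keratinocytes. Per the labels' protocols, skin was incubated in ammonium thiocyanate, the epidermis was lifted off the dermis with forceps, and amplified RNA was labelled with Cy3. The number of mice behind each RNA sample is not given in the sources used here.

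Per the file headers, both arrays were quantified with Agilent Feature Extraction 10.7.3.1 on an Agilent mouse design annotated on mm9, and both came from 1 slide and 1 scan day, so slide and scan day do not separate the groups. The deposited scanner files give each spot's intensity on a linear scale, after background subtraction and detrending within the array per the file headers, with an error from the software's error model and marks for saturation, signal over background and non-uniform spots. A table of log2 values deposited by the authors was also compared. Its columns sum to 0 for every probe (largest absolute sum 1e-06), so each probe was centred over the 2 arrays, and the medians of the control and knockout columns were 0.14 and -0.14. Its knockout minus control difference had a Pearson r of 1.00 across probes with the scanner values and a median offset of -0.00 from them. These values settle its log2 scale, centring and direction. The level of a probe on either array cannot be had from it.

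The main values were log2 processed signals minus the 75th percentile over non-control probes of each array. Spots marked as outliers were left out, spots of a probe were averaged, and control spots were removed. A probe counted as measured on an array when it was well above background and not saturated. Probes were named only through accessions in a RefSeq gene table of assembly GRCm38.p6, used for names and not for positions. It named 26690 of 41174 probes (64.8%), and 14484 stayed without a name. A gene was represented by its probe with the highest mean scaled signal. Where all probes of a gene were not well above background on 1 array, the gene has only a bound there, written as at least N-fold: the bright value against the higher of the dim probe's own signal and the lowest signal among probes well above background.

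With 1 array per group there is no replicate check, so no p-value was computed and genes were called by size alone, at 2-fold. The errors given after ± are standard errors of a log2 difference from the scanner software's error model. They cover technical error within these arrays and not differences between mice. For each of 39 gene lists, the median difference was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these 2 arrays and is not a test of genotype, since members of a list can vary together. The calling and ranking code was tested on simulated data for this comparison, with 12396 genes and 200 of them altered. It called 91.0% of genes simulated at a log2 difference of 1.5, 100% at 3.0, and 0.0984% of unaltered genes, with a noise SD of 0.3 that is smaller than the spread in these data.

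The lists, the rule for naming genes and the main alternatives were fixed before the data were examined. Named genes were Nfkbiz, the 12 genes furthest apart in each direction among those at least 2-fold apart under every scaling, the 5 largest bounds each way, up to 4 members of each list with the largest difference, further 2-fold members of the keratinocyte, antimicrobial, cytokine and interferon lists, and all sex-linked and reference genes. Symbols that are only placeholders were left out, and some genes that the rule names are not reported here. Alternatives were median scaling, quantile normalization, cyclic loess and normexp background correction with an offset of 50 (limma 3.58.1 in R 4.3.3), the mean over probes, the authors' table, fold thresholds of 1.5 and 3, and other filters on dim probes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the rest.

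Several choices were made after seeing the data. Normexp was run on median spot signals, because the files hold no mean signal, and its first fit failed on the knockout array, where 1 spot had an extreme local background, so it was fitted without spots marked as non-uniform. Normexp was counted among the scalings when the alternatives were fixed. A version of the scaling tests without it was added once its outcome was known, and both versions are given. In the tests of keratinocyte share and of T-cell and Langerhans cell share, the bounds were also reset after their values were known, to ask for a gap beyond the SD of the members, which left both explanations open, and the members at least 2-fold lower were then set apart in a further test against the bound of -1 that had been written first. Probes within 3 rows and 3 columns of a non-uniform spot were left out in an added alternative. A check for neighbouring spots with like differences was tried in 3 forms. The first 2 did not separate genes named for their size from random genes, and the last, with a minimum of 5 such neighbours, was set after the counts of the named genes had been seen. The hypotheses drew on 4 further gene lists written after the main results, as stated beside them.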

Results

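The series compared epidermis of a control mouse genotype with epidermis of a genotype labelled as lacking, in keratinocytes, IκBζ, the nuclear IκB protein encoded by Nfkbiz, in the steady state. The series title places the comparison in a study of systemic autoimmune inflammation and the skin microbiota. Each genotype was measured on 1 array, so no difference below has a replicate check and none was tested. The 75th percentile of signal was 205 on the control array and 239 on the knockout array. Signals were well above background for 56.3% of probes on each array, no probe was saturated, and the median SD of replicate spots was 0.11 and 0.08 on the log2 scale. Of 18206 named genes, 12396 were measured on both arrays and 4708 were not well above background on either. The number of arrays limits the precision.

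Nfkbiz itself was lower on the knockout array, with a signal of 1760 against 3100 on the control array (log2 difference -1.04 ± 0.20, 2.06-fold). Median scaling gave -0.70. Among the probes that could be named here, 1 reads the gene, and neither the deleted exons nor the place of the probe is given in the sources used here. A probe outside the deleted part would check nothing. The epidermis also holds cells in which the keratin 5 promoter is not active.

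The knockout array had much lower signals for some stress keratins, small proline-rich cornified envelope proteins and antimicrobial proteins, though not for other members of the same families, and lower signals for markers of melanocytes, skeletal muscle and red blood cells. Krt16, a keratin of stressed and wounded epidermis, was 13.6-fold lower (-3.77 ± 0.20), Lce3c 7.04-fold lower and the β-defensin Defb14 5.44-fold lower. At least 2-fold higher were 6 of 20 interferon-stimulated genes and 15 of 57 hair shaft and growing follicle genes, mostly keratin-associated proteins. Most genes lay close together on the 2 arrays, with 92.5% of those measured on both within 2-fold.

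Among genes measured on both arrays, 370 (2.98%) were at least 2-fold higher on the knockout array and 554 (4.47%) at least 2-fold lower. At 4-fold the counts were 45 and 87. A further 96 genes measured on the knockout array alone were higher by their bound, and 179 measured on the control array alone were lower. Pearson r across genes was 0.975, and genes are not independent replicates. The balance of directions depends on scaling. Higher genes made up 40.04% of those 2-fold apart under the 75th percentile, 78.1% under median scaling and 50.1% under quantile normalization. Median scaling moves every gene by 0.35 in log2. Relative to the median gene, 417 genes were higher and 489 lower under both the 75th percentile and the median. Under normexp the counts were 184 and 228, and 168 and 192 genes were at least 2-fold apart the same way under every scaling. Of the lists below whose medians lay within the central 95% of random lists, 13 had a median that changed sign under at least 1 other scaling. Since median scaling moves all genes alike, a sign change under it leaves a list's distance from the median gene as it was. That distance was -0.15 for cornified envelope genes and -0.21 for the NF-κB family under both the 75th percentile and the median. Of 98 named genes at least 2-fold apart on both arrays, 13 were under 2-fold with median scaling and 31 with normexp. Of 250 genes 2-fold apart with several measured probes, 30 had probes that disagreed in sign.

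**Figure D1:**
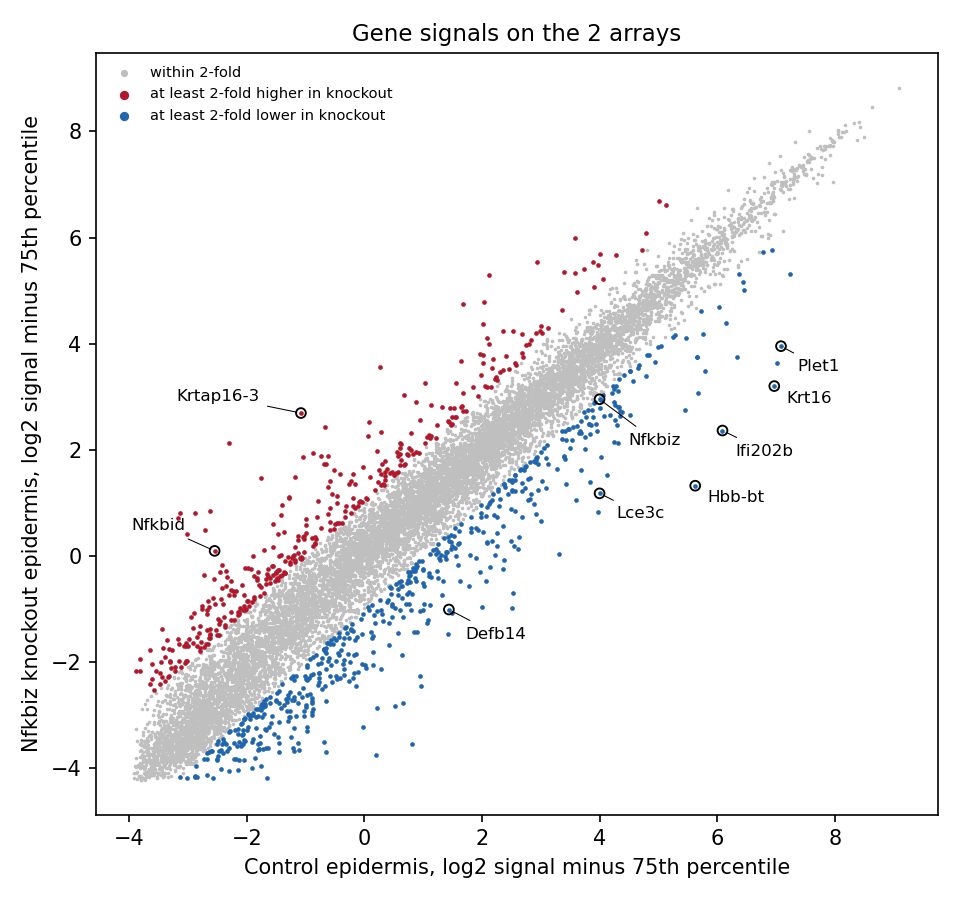
Scaled log2 signal of each gene measured on both arrays, control on the x axis and knockout on the y axis, 1 point per gene, with genes at least 2-fold higher in red (370) and at least 2-fold lower in blue (554). Circled genes are named in the text, and Krt16, Ifi202b and Hbb-bt lie far below the diagonal while Krtap16-3 lies far above it.

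The 12 genes furthest down included Myl1, a skeletal muscle myosin light chain (20.5-fold), the β-globin gene Hbb-bt (19.7-fold), and Alas2, the erythroid enzyme that starts haem synthesis (15.4-fold). Krt16 followed, then Ifi202b (13.2-fold), a member of an interferon-inducible family, and Abhd2 (11.3-fold). Fkbp5, a glucocorticoid-induced co-chaperone, was 10.6-fold lower. The nuclear noncoding RNA Neat1 was 10.4-fold lower, from a signal of 25200 to 2830. Depp1 was 10.1-fold lower, Snhg3 9.60-fold lower and Ch25h, which makes an oxysterol, 9.36-fold lower. Among genes measured on the control array alone, Tnfsf18 was at least 40.6-fold lower, Mrgpra1 at least 11.6-fold, Elmo1 at least 9.80-fold, Kif17 at least 9.72-fold and Syt6 at least 9.31-fold.

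Of the 12 genes furthest up, 5 encode keratin-associated proteins of hair: Krtap14 (15.5-fold), Krtap19-9b (14.8-fold), Krtap16-3 (13.7-fold), Krtap6-5 (11.2-fold) and Krtap6-1 (9.46-fold). Pyy, which encodes peptide YY, was 9.79-fold higher, Mex3b 9.21-fold, Zfp296 9.13-fold and Ier5l 8.62-fold. Rfx8 (12.9-fold) and the kallikrein Klk4 (10.67-fold) were also in this set, but each had 5 neighbouring spots with a like 4-fold difference. Rbm26 (21.8-fold) lay near a non-uniform spot, and its probes differed by 0.43 and 4.45. Among genes measured on the knockout array alone, Irs3 was at least 29.8-fold higher, also with 5 such neighbours, Krtap19-3 at least 13.1-fold, the interferon-γ-induced GTPase Iigp1 at least 11.5-fold, Krtap19-2 at least 9.49-fold and Slc4a10 at least 9.08-fold. Kif17, among the lower genes, had 7 such neighbours.

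Stress and wound keratinocyte genes had 8 of 17 measured members at least 2-fold lower and 2 higher, with a median of -0.40, at percentile 0.24 of random lists. Besides Krt16, the stress keratins Krt6a and Krt6b were 4.84-fold and 3.78-fold lower, the protease inhibitor Serpinb2 3.75-fold, Sprr1b 3.21-fold, the urokinase receptor Plaur 3.03-fold and the EGF receptor ligand Epgn 2.03-fold, and Mmp10 was at least 2.15-fold lower. Krt17, also a stress keratin and chosen after its value was seen, had signals of 36700 and 42800 before scaling. The 75th percentiles of these control and knockout arrays were 205 and 239. Another EGF receptor ligand, Hbegf, was 2.27-fold higher, and the protease Mmp9 2.14-fold higher. The median was -0.05 under median scaling.

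Cornified envelope and terminal differentiation genes had 10 of 43 members at least 2-fold lower and none higher, with a median of -0.19 (percentile 1.91) that turned to 0.16 under median scaling. The lower members were mostly small proline-rich proteins, including Sprr2d (8.38-fold), Sprr2h (5.76-fold), Sprr1a (3.38-fold), Sprr2g (3.13-fold) and Sprr2f (at least 6.81-fold). The late envelope genes Lce3c, Lce3f (at least 5.88-fold, near a non-uniform spot) and Lce1g (2.16-fold, its other measured probe at -0.51) and the repetin gene Rptn (3.74-fold) were the others, with Sprr1b. Not all small proline-rich genes were lower: Sprr4 and Sprr2a1, chosen after their values were seen, differed by 0.73 and 0.29. Basal keratinocyte and hemidesmosome genes had a median of -0.39 (percentile 0.07, -0.04 under median scaling), with 1 of 14 members at least 2-fold lower. Suprabasal genes had a median of 0.02 (percentile 88.6), with only the metallothionein gene Mt4 2-fold apart, 3.69-fold higher. Cell junction genes had 6 of 27 members lower, among them the desmosomal cadherin Dsg3 (4.88-fold), the connexin gene Gjb2 (4.47-fold), Cldn4 (3.60-fold) and Cldn1 (2.39-fold), with a list median of -0.15 (percentile 10.4) that turned to 0.19 under median scaling. The epidermal lipid barrier list had a median of -0.12 (percentile 17.4, 0.23 under median scaling), and 1 member past 2-fold, Elovl7, at -1.02. Its other measured probe was at -0.41, and it was at -0.68 under median scaling and -0.91 under normexp.

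Antimicrobial proteins had a median of -0.35 (percentile 2.36, -0.00 under median scaling), with 3 of 16 members lower and 2 higher. The protease inhibitor Slpi was 5.50-fold lower, Defb14 5.44-fold and Adm 3.53-fold, while the calprotectin subunit gene S100a8 was 2.32-fold higher, its partner S100a9 differed by -0.45, and Wfdc12 was at least 3.32-fold higher. Among IL-17A and IL-36 responsive keratinocyte genes, Defb14 and Ccl20 (3.41-fold) were lower, S100a8 was higher, and Il6, measured on the knockout array alone, was at least 3.88-fold higher. That list's median was -0.05 (percentile 61.4) and was above 0 under median scaling, quantile normalization and loess.

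The NF-κB and IκB family list, which left out Nfkbiz, had a median of -0.26 (percentile 2.48) that turned to 0.092 under median scaling. Bcl3, another nuclear IκB protein, was 4.16-fold lower (-2.06 ± 0.20) and Tnfaip3, which encodes the ubiquitin-editing inhibitor A20, was lower by a log2 difference of -1.32 ± 0.20. Nfkbid, a further nuclear IκB gene, was 6.26-fold higher (2.65 ± 0.25). Chemokines and colony-stimulating factors had 4 of 15 members lower and 1 higher (median 0.04, percentile 77.2). Ccl20, Cxcl16 (2.74-fold), Cxcl12 (2.35-fold) and Ccl7 (at least 2.89-fold) were lower, and the interferon-induced chemokine gene Cxcl9 was 3.44-fold higher. The IL-1 family had a median of 0.17 (percentile 90.9), with Il1f10 2.16-fold higher, the IL-17, IL-23 and IL-22 axis -0.02 (percentile 58.3), and type 2 cytokines and epithelial alarmins -0.36 (percentile 7.59). Neither of the last lists had a member past 2-fold.

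Interferon-stimulated genes had the highest list median in the main setting, 0.95, above all 10000 random lists, with 6 of 20 members at least 2-fold higher and none lower. Among them, Rtp4 was 3.47-fold higher, Oas1a 2.95-fold, the ubiquitin-like Isg15 2.56-fold, Usp18 2.11-fold and Xaf1 2.04-fold. With dim members at their bounds the median was 0.52, and under normexp it was 0.20. Both were below the medians of MHC class II genes (0.59 and 0.54) and proliferation genes (0.54 and 0.41), so the rank was lost. MHC class II presentation genes had a median of 0.62 (percentile 99.9, 0.97 under median scaling), with H2-DMa, the invariant chain gene Cd74 and H2-Aa at 0.78, 0.75 and 0.67 and no member past 2-fold. Innate immune sensors had a median of 0.23 (percentile 97.8, 0.57 under median scaling), although Irak3 and Nod2 were 3.81-fold and 3.33-fold lower. Proliferation genes had a median of 0.54 (0.88 under median scaling), above all random lists, with Plk1 and Aurka 2.09-fold and 2.01-fold higher among 19 members.

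**Figure D2:**
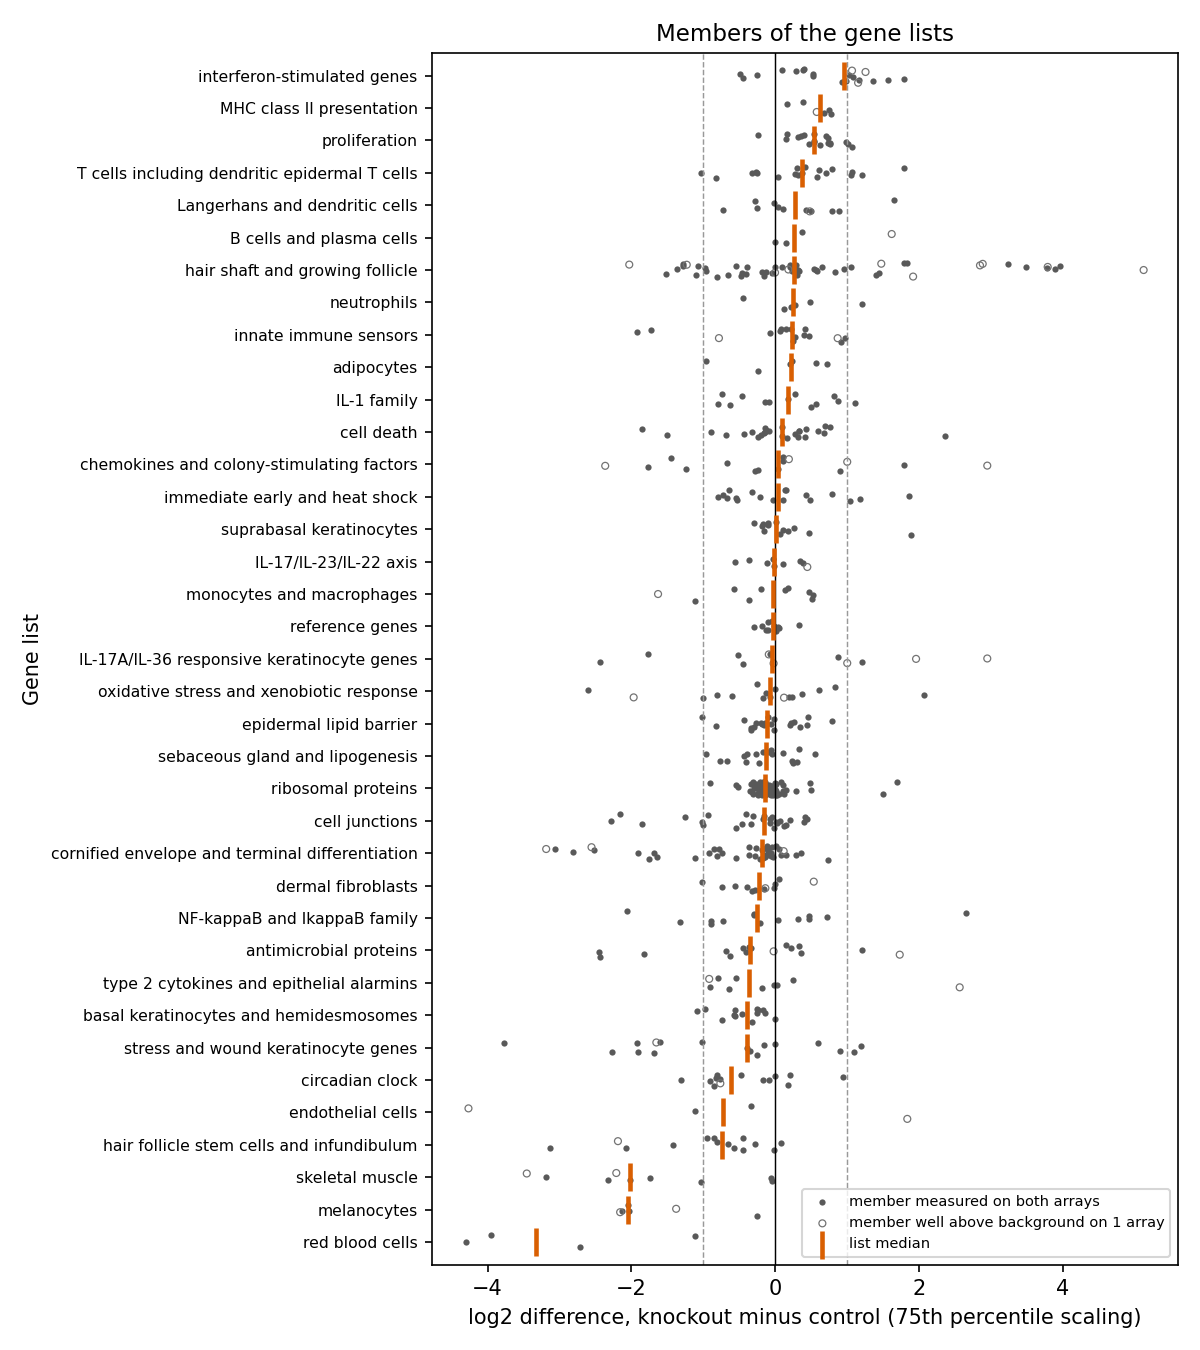
Log2 difference (knockout minus control, x axis) of the members of each gene list with at least 4 measured members (y axis), filled where measured on both arrays and open where well above background on 1, with orange bars at list medians and dashed lines at 2-fold. Red blood cell genes lie lowest (-3.33) and, in this main setting, interferon-stimulated genes highest (0.95). With dim members at their bounds the interferon median was 0.52, below that of MHC class II genes (0.59). List medians of NF-κB family and cornified envelope genes turned above 0 under median scaling, as did other medians near 0. That scaling shifts all genes alike and leaves distances from the median gene unchanged.

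Hair genes split. Of 57 measured hair shaft and growing follicle genes, 15 were at least 2-fold higher, mostly keratin-associated proteins, and 8 lower, with a median of 0.25 (percentile 99.97) that was 0.60 under median scaling and 0.075 under normexp. The lower members, chosen after their values were seen, were the inner root sheath genes Krt27 (2.88-fold), Tchh (2.58-fold), Krt71 (2.44-fold) and Krt25 (2.15-fold), with Padi3, Lef1, Krtap17-1 and Krtap13. Hair follicle stem cell and infundibulum genes were lower, with a median of -0.74 (-0.39 under median scaling), below all random lists, and 4 of 14 members past 2-fold: Plet1 (8.74-fold), the stem cell gene Lgr5 (at least 4.56-fold), the transcription factor gene Lhx2 (4.21-fold) and Cd34 (2.69-fold). Sebaceous gland and lipogenesis genes had a median of -0.13 (percentile 32.9, 0.22 under median scaling) and no member past 2-fold.

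Markers of other cell types differed between the arrays. Melanocyte genes had a median of -2.04 and 4 of 6 measured members lower, with Dct 4.38-fold, Tyrp1 4.15-fold and Pmel 4.09-fold lower. Skeletal muscle genes had a median of -2.02, with 7 of 9 lower, including Acta1 (9.11-fold). All 4 measured red blood cell genes were lower, with a median of -3.33. All 3 medians lay below all random lists and were -0.82, -0.75 and -2.30 under normexp. Endothelial genes had a median of -0.73 (percentile 12.6, 4 measured) and dermal fibroblast genes -0.22 (percentile 16.5, 12 measured, 0.13 under median scaling). T-cell genes, including those of dendritic epidermal T cells, had a median of 0.37 (percentile 99.5, 0.72 under median scaling), with Cd69 3.45-fold, Cd247 2.29-fold (its other measured probe at -0.33), Itgae 2.10-fold and Klrd1 2.08-fold higher and Xcl1 2.06-fold lower. Cd207, the langerin gene of Langerhans cells, was 3.13-fold higher in a list with a median of 0.27 (percentile 94.3). Medians were 0.25 for neutrophils (percentile 89.1), -0.03 for monocytes and macrophages (60.9), -0.41 for mast cells (38.9), 0.26 for B and plasma cells (86.7) and 0.22 for adipocytes (89.3).

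Circadian clock genes had a median of -0.62 (percentile 0.02, -0.27 under median scaling), and 1 member past 2-fold, Per2, at -1.31. Its other measured probe was at -0.52, and it was at -0.96 under median scaling and -0.57 under normexp. Immediate early and heat shock genes had a median of 0.04 (percentile 94.2), with Ier3 3.62-fold, Hspa8 2.26-fold and Ier2 2.05-fold higher. The cell death list had a median of 0.09 (percentile 85.5), with Bbc3 5.12-fold higher and Tnfrsf10b and Pmaip1 3.60-fold and 2.84-fold lower. The oxidative stress and xenobiotic list had a median of -0.07 (percentile 47.8), with Srxn1 6.08-fold lower and Aldh3a1 4.19-fold higher. The 12 reference genes ranged from -0.29 for Ywhaz to 0.33 for B2m, with a median of -0.03 (percentile 63.7) whose sign depends on scaling, and 73 ribosomal protein genes had a median of -0.14 (percentile 16.3), which turned above 0 under median scaling, quantile normalization and loess. Xist was measured on both arrays, with signals of 1770 and 1300 at its brightest probe, and its 4 measured probes differed by -0.67 to -2.04. Of the Y-linked genes, only Kdm5d was well above background, at 23.4 and 23.0. The median of the sex-linked list was -0.46 (percentile 17.0) over just 2 measured genes, too few to read.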

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

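Probes without a gene name here take no part in the comparison of genes. Of their signals above the control array, those below met a stricter rule: at least 4-fold higher in all of several probes of a transcript, or a log2 difference of at least 8 in 1 probe. A transcript read by 2 probes that could not be named here had a mean log2 difference of 2.56, from 2.88 and 2.25, with signals of 504 and 44.7 on the control array and 4340 and 248 on the knockout array. A single unnamed probe had a log2 difference of 12.84, with signals of 2.79 and 24000, and it lay within 3 rows and 3 columns of a spot marked as non-uniform. Its control signal was below 12.7, the lowest signal well above background on that array, so the exact size of this difference is not known.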

How the results depend on the processing

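Leaving out probes near non-uniform spots was chosen after seeing the data, and the other alternatives before. No paired analysis was possible because each genotype has 1 array. Nfkbiz was lower throughout, from -1.04 to -0.70 under median scaling. Counts at least 2-fold higher and lower on both arrays (370 and 554) were 1009 and 283 under median scaling, 184 and 228 under normexp, 1241 and 1663 at 1.5-fold, 103 and 189 at 3-fold, 560 and 832 with genes measured on at least 1 array, and 662 and 1442 with no filter on background. By bound, the 96 knockout-only genes became 11 under normexp, 154 at 1.5-fold and 52 at 3-fold, and the 179 control-only genes 109 under median scaling, 111 under both quantile normalization and loess, 20 under normexp, 381 at 1.5-fold and 81 at 3-fold. Thresholds and filters move counts by construction, normexp adds an offset that shrinks dim differences, and median scaling adds 0.35 to every gene. The cause of other moves was not tested. The authors' table has no level per array, and its differences set on the scanner levels of the control array gave bound counts of 96 and 182.

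List medians turned to 0.092 for the NF-κB family and 0.16 for cornified envelope genes under median scaling. Among lists within the central 95% of random lists, 10 further medians changed sign under median scaling and 13 under at least 1 scaling. Median scaling adds the same amount to every gene, so changes under it leave each list's distance from the median gene as it was. Of the other comparisons of list medians, 225 moved by less than the spread of replicate spots and 85 by more. For named genes, 882 moved by less than their technical error and 282 by more, with none past 2-fold changing sign. Signal over background limits genes near the lowest signals well above background, 12.7 and 12.1.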

Other observations

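Of the tests below, those on 4 further gene lists had their expected outcomes written before those lists were measured. All others were chosen after the result was seen, and leaving normexp out of the scaling tests was chosen after its outcome was known.

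A group of interferon-γ-induced genes, noticed among the highest genes and so chosen after their values were seen, was higher on the knockout array. Irf1, a transcription factor gene, was 8.45-fold higher, Irgm2 6.34-fold, Igtp 4.59-fold, the guanylate-binding protein gene Gbp2 4.55-fold and Irgm1 4.39-fold, and Iigp1 was at least 11.5-fold higher. The glucocorticoid-responsive genes Fkbp5, Depp1 and Per2, also noticed afterwards, were 10.6-fold, 10.1-fold and 2.48-fold lower, Per2 by 1 of its 2 measured probes only. Hif3a, also of this set, had its brightest probe at signals of 335 and 7.56, the latter not well above background, but a probe measured on both arrays differed by only -0.37. A transcript without a name here had the lowest paired probes, at -5.59 and -5.29.

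Stress and wound keratinocyte genes were lower on the knockout array, with a list median of -0.40. The joint median of 27 basal and suprabasal keratinocyte genes was -0.17 (SD of members 0.54), with the basal list at -0.39. That joint median lay above -1 by more than the SD. However, the 8 members at least 2-fold lower were picked by the same bound of -1. The SD also measures spread between genes and not the error of a median. Fewer keratinocytes therefore cannot be told apart here, for those 8 members or for the shift of the list median. For the 2-fold calls as a set, scaling cannot be told apart: 5 of the 8 lower members stayed at least 2-fold lower under all settings, and 7 of 8 when normexp was left out. Relative to each setting's median gene, the list median was below 0 throughout, from -0.28 under normexp to -0.42 under quantile normalization. The list's place below the median gene thus did not depend on the scaling. Under normexp, whose offset shrinks dim differences, Plaur went from -1.60 to -0.73 and Epgn from -1.02 to -0.80. Krt16 was at -3.65 there and at -3.42 under median scaling. Mmp10, not well above background on the knockout array, had a bound of -1.10 in the main setting and a difference of -0.43 under normexp. Reduced expression in knockout keratinocytes and differences between mice may also account for the pattern, and neither was tested.

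Markers of melanocytes, muscle and red cells were lower on the knockout array, while the first endothelial list, with 4 measured members, lay at percentile 12.6. A dermal fibroblast median of -0.22 argues against more dermis in the control sample as the whole cause of falls of this size. With 10 of 12 fibroblast genes below 0, some more dermis or deeper tissue there stays open. Fewer growing follicles is argued against by a further list of growing-follicle genes at percentile 64.2 and the 15 higher hair shaft genes. Lower inner root sheath genes such as Krt27 (-1.53), Tchh (-1.37) and Krt71 (-1.28) and the stem cell list at -0.74 go the other way, so a difference in part or stage of the follicles stays open. A further endothelial list, with a median of -0.79 over 10 genes at percentile 1.13, is consistent with more vessels and blood in the control sample, which does not cover melanocytes or muscle. Peeling of the epidermis and the genotype stay untested.

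Interferon-stimulated genes were higher on the knockout array as a list, with 6 of 20 members at least 2-fold higher and 3 below 0. Ifi202b, of an interferon-inducible family but not in the list, was 13.2-fold lower. With all settings that had been fixed as scalings, the lowest relative median of the interferon list was 0.23, under normexp, the outcome written for scaling. Normexp is a background correction whose offset shrinks dim differences. With it left out, the relative median was 0.996 under the 75th percentile and the median, 0.93 under quantile normalization and 0.92 under loess. These values argue against scaling between the arrays alone as the cause of the list's place above the median gene. Whether the background correction accounts for it stays open. Noise of dim signals is argued against by a relative median of 0.996 for the 5 members above the 75th percentile on both arrays. The T-cell and Langerhans lists had a joint median of 0.37 against 0.95, a gap within the SD of the members (0.67). That SD measures spread between genes and not the error of a median, so it cannot decide the question. More T cells and Langerhans cells therefore stays open. A further list of 21 interferon-γ inducible genes had a median of 0.73 at percentile 100, with 4 members at least 2-fold higher and a median of 0.42 with dim members at their bounds, consistent with a shared interferon-γ response.

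A shared glucocorticoid response was a hypothesis from Fkbp5, Depp1, Per2 and Hif3a. A further list of 16 glucocorticoid-responsive genes had a median of 0.06 at percentile 88.9, so it was not lower, and the hypothesis found no backing.

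Neighbouring spots give a caution on single genes. Of 34 genes named for their size, 5 had at least 5 neighbouring spots with a like 4-fold difference (14.7%), against 3 of 300 random genes (1%). The minimum of 5 was set after the counts had been seen. With any like neighbour the shares were 38.2% and 37%. The 5 genes were Irs3, Rbm26, Rfx8, Klk4 and Kif17. Krt16, also named for its size, had 4 such neighbours, just under that minimum. Unnamed probes measured on both arrays were lower more often than higher, with 379 of 4065 (9.32%) at least 2-fold lower and 103 (2.53%) higher.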
